A study of Mus musculus with 24 samples.

How the data were processed

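The series measured RNA of epithelial cells isolated from the proximal colon of mice with 2, 1 or 0 working copies of Ptpn2. The labels put 4 mice in each of 3 genotypes, wild type (WT), heterozygous (HET) and knockout (KO), from 3 litters. Replicates 1 and 2 of each genotype came from litters 1 and 2, and replicates 3 and 4 from litter 3. All mice were female except WT replicate 4 and HET replicate 4. Per the series design text, the mice were 21 days old, and the RNA was hybridised to 2 targeted probe panels, each extended by 30 further targets. Every mouse was run on both panels, which gives 24 assays. Which table held which panel was read from its genes, and the panels are called the cancer pathway panel and the immune panel here.

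The values used were the normalized signal per probe and mouse, which the authors deposited as 1 table per panel. Per the series design text, the authors normalized each panel on its own with nSolver Analysis Software 4.0 and then combined them. The background step and the reference genes they used are not given in the sources used here. Low probes sat at a repeated lowest value in each assay, between 1.00 and 1.51 in the cancer pathway panel and between 10.71 and 18.97 in the immune panel. A share of 19.6% to 28.9% of the cancer pathway probes and 8.9% to 23.7% of the immune probes was at that floor. The signal of all probes of an assay summed to between 374398 and 469527 in the cancer pathway panel and between 572124 and 922790 in the immune panel. Whole barcode counts were not used, so the counting depth of an assay is unknown, and no test for counts was run. The authors' deposited table of comparisons gives, per the file headers, log2 fold changes with standard errors, p-values and adjusted p-values for KO and for HET against WT. The header names the adjustment FDR for KO and BY for HET. The smallest adjusted p-values for KO match Benjamini-Yekutieli (BY) too, which is stricter than the Benjamini-Hochberg adjustment used here. A consolidated table that the authors deposited served for its other columns only, the accession and class of each probe. It also holds 12 sample columns whose names match no label, and those were not used. A probe for Ptpn2 itself was not analysed here, so the genotype labels were not checked against the targeted gene.

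Probes were named through a RefSeq table of assembly GRCm38.p6, used for names only. Of 1413 genes, 1394 were named by accession and 18 by symbol, 1 kept its name from the files (DEFA6), and 33 names changed. The panels shared 179 genes. Control probes, 14 per panel, and 30 reference genes were left out. Values were tested as log2(value + 1), so a fold change is on that scale and understates the change of low genes. A gene on both panels entered as the mean of its 2 log2 values per mouse. Genes with a mean below 20 over the 12 mice, 445 in number, were left out. This left 938 genes, of which 352 were on the cancer pathway panel only, 464 on the immune panel only and 122 on both.

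Each comparison (KO against WT, HET against WT, KO against HET) was fitted with limma 3.58.1 (lmFit, eBayes) in R 4.3.3 over all 12 mice without a litter or sex term. P-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. The limma p-values of single genes measure the spread between mice. Of 35 gene lists written before the data were examined, 32 had at least 3 tested members. Some genes are on several lists, so the list results are not independent of each other. After the data were seen, 1 gene that is not reported here was taken out of the interferon gamma and JAK-STAT lists, and their results are without it. The lists were tested with camera from limma at a preset correlation of 0.01 between genes, and again with an estimated correlation and with fry. At that preset the genes of a list count as nearly independent. Where they vary together, a small camera p therefore does not measure the spread between mice. A list's level in a mouse is the mean log2 value of its tested members, and levels were compared by exact two-sided permutation of 4 mice against 4, whose smallest p is 0.0286. That permutation moved mice freely across litters. A correlation between list levels over the 12 mice was tested by permutation. Named genes followed a rule fixed beforehand: the 12 highest and 12 lowest fold changes past the threshold in each comparison, or the 5 smallest p-values where fewer than 5 genes passed, and for each list up to 4 members with the smallest p in KO against WT. Genes named outside this rule are said to be so. Tables were prepared in Python 3.11.15 with pandas 2.3.3 and plots drawn with matplotlib 3.10.9.

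The labels give the litters, so mice of a litter are paired. Deviations from the genotype means correlated at a mean r of 0.29 across genes for the 18 pairs of litter mates of different genotype, with a range from -0.61 to 0.63, and at -0.17 for other pairs. Each of the 12 mice correlated best with a mouse of its own litter. The alternatives were another pseudocount, filter, normalization, litter or sex term, subset of mice, variance model, panel for shared genes, adjustment and list test, and leaving out each mouse in turn. Centring on the reference genes, exact permutation of list levels and leaving out a pair of mice were added after seeing the data. The fit was tested on simulated data made from the 938 genes with 200 genes changed in KO against WT. Genes were drawn independently of each other and without a litter effect. Over 20 runs the fit recovered 67.6% of changes of 1 on the log2 scale and 93.6% of changes of 2, and 4.2% of its calls were false. A changed list was called in 20 of 20 runs. The real genes vary together and by litter, so these rates need not hold for them.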

Results

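Ptpn2 encodes a tyrosine phosphatase that acts on JAK kinases and STAT proteins and so limits interferon and cytokine signalling. Mice without it die within 3 to 5 weeks of birth, per the series design text, and colon epithelial isolates were taken from littermates at 21 days. The data comprise 24 assays of 12 mice, 4 each of WT, HET and KO, on a cancer pathway panel and an immune panel. The comparisons ask how loss of 1 or both copies of Ptpn2 changes these transcripts. The group means below are normalized values on the linear scale, given with the SD of 4 mice.

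KO isolates had lower values of Il18, an epithelial cytokine of the inflammasome pathway, and of the kinase gene Stk26 than WT isolates, and higher values of Casp9 and of the T cell receptor components Cd3e and Cd3g. These were the 5 genes with the smallest p, and none passed the threshold. Il18 was 1690 ± 240 (SD, n = 4) in KO and 2840 ± 395 (SD, n = 4) in WT, a log2 fold change of -0.75 (SE 0.22), and each KO mouse lay below each WT mouse. Stk26 was 35.5 ± 18.3 in KO and 78.1 ± 26.8 in WT, with a log2 fold change of -1.17 (SE 0.34). Casp9, the initiator caspase of the mitochondrial death pathway, was 28.6 ± 9.26 against 15.1 ± 3.14, with a log2 fold change of 0.84 (SE 0.25). Cd3e was 45.6 ± 14.1 against 24.8 ± 8.57 and Cd3g 76.7 ± 38.8 against 34.6 ± 13.6, with log2 fold changes of 0.85 and 1.06. The limma adjusted p of all 5 genes was 0.999. The count of genes past the threshold was 0 of 938 with limma, and 27 genes had an unadjusted p under 0.05, 20 higher and 7 lower in KO, where 47 would arise by chance.

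Of the 32 lists, camera called T and NK cell, type I interferon, MHC class I and MHC class II genes as higher in KO than in WT isolates, and stem cell genes as lower. The T and NK cell list had 13 of 16 members higher and a median log2 fold change of 0.52, with camera adjusted p = 8.94e-05. Among its members, the granzyme gene Gzma was 505 ± 303 in KO and 152 ± 157 in WT, and the cytokine receptor gene Il2rb 67.3 ± 26.4 and 30.8 ± 16.5. The type I interferon-stimulated list had 24 of 26 members higher and a median of 0.68, with camera adjusted p = 0.000759. Ifit3 and Ifit1, antiviral effectors, had log2 fold changes of 1.44 and 1.13, and the 2'-5'-oligoadenylate synthetase-like gene Oasl1 had 0.70. The MHC class I list had a median of 0.66 and the MHC class II list 1.47, with camera adjusted p of 0.00225 and 0.0135. H2-K1, a classical class I heavy chain, was 27200 ± 11700 in KO and 15900 ± 6410 in WT. The class II chains H2-Aa, H2-Ab1 and H2-Eb1 had log2 fold changes of 2.16, 1.88 and 1.96, with SE of 1.32, 1.12 and 1.16. The stem cell list was lower, with 8 of 8 members below WT, a median of -0.16 and camera adjusted p = 0.0281. Sox9, Axin2 and Lgr5 had log2 fold changes of -0.42, -0.41 and -0.40. All 5 calls were lost with an estimated correlation between genes, each at adjusted p = 0.647 with an estimated correlation. Adjusted over the list alone, 0 members of any of these lists passed with limma, as over all genes tested.

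The interferon gamma list did not pass in this comparison, with a median of 0.56 and camera adjusted p = 0.171. Its level overlapped between genotypes. WT replicates 1 and 3 lay at 9.37 and 9.25, within the range of KO replicates 1, 2 and 4, which lay at 9.46, 9.18 and 9.01. KO replicate 3 lay at 7.37, below WT replicate 4 at 7.94. Markers of epithelial identity and of absorptive colonocytes were measured beside them. The brush border enzyme gene Alpi was 7990 ± 2320 in KO and 3750 ± 1600 in WT, and the mucin gene Muc2 44600 ± 32600 and 61200 ± 15900, neither past the threshold. The epithelial identity, absorptive colonocyte and goblet cell lists had medians of 0.24, 0.21 and -0.04, and camera did not call them. Of the other cell types, lists of macrophages and dendritic cells, B and plasma cells, granulocytes and mast cells, fibroblasts and smooth muscle, and endothelium had medians of 0.03, -0.11, 0.01, -0.25 and -0.08, and none was called. Cell cycle, DNA repair, Wnt, Notch and TGF-beta lists had medians of -0.04, -0.06, 0.03, -0.09 and -0.03 and were not called.

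Further lists of signalling and defence were not called in KO against WT either. Components of the JAK-STAT pathway, through which cytokine receptors signal, had a median of 0.20 over 22 members, with camera adjusted p = 0.063, and the SUMO ligase gene Pias1 had a log2 fold change of 0.58. Junction, iron handling, immediate early, EGFR family, autophagy and complement lists had medians of 0.24, 0.18, 0.18, 0.16, 0.02 and 0.10. The lists of pattern recognition, cell death and Paneth and deep crypt secretory cells had medians of 0.10, 0.17 and -0.21. The p53 target and cell cycle inhibitor list had a median of 0.13 and an exact permutation p of 0.0286, which did not pass after adjustment over the lists. Median, mean and camera direction differed in sign for several lists. The antimicrobial list had a median of 0.08, a mean of -0.04 and a downward direction, and the inflammatory cytokine list a median of -0.01, a mean of 0.19 and a downward direction. The Wnt and the macrophage and dendritic cell lists each had a median of 0.03, a mean of -0.01 and a downward direction. EGFR family, autophagy and granulocyte and mast cell lists had positive medians and means of 0.08, 0.02 and 0.06 with a downward direction.

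The KO against WT results depended on single mice. Without WT replicate 2 the type I, MHC class I and MHC class II medians were 0.34, 0.39 and 0.46 and their calls were lost, and H2-Aa, H2-Ab1 and H2-Eb1 had log2 fold changes of 0.75, 0.69 and 0.75, Oasl1 0.44 and Il2rb 0.92. The type I call was also lost without WT replicate 4 or KO replicate 1, the class I call without KO replicate 2, and the class II call without KO replicates 1 or 2. Without KO replicate 1 the type I median was 0.39, and Ifit3 and Ifit1 had log2 fold changes of 0.95 and 0.70. Without KO replicate 3 the type I, MHC class I and MHC class II medians were 1.18, 0.90 and 2.20, Ifit1 had 1.72, H2-K1 1.11 and Muc2 -1.13, and the type I median was 1.10 without WT replicate 3. Muc2 had -0.45 and -0.40 without KO replicates 1 and 2. The stem cell call was lost in 5 of 12 fits that leave out 1 mouse (WT replicates 1, 3 and 4 and KO replicates 2 and 4), with medians of -0.03 and -0.06 without KO replicates 2 and 4 and of -0.27 and -0.25 without KO replicates 1 and 3. Without KO replicate 2, Axin2 had -0.27 and Lgr5 -0.06. The T and NK cell list kept its call in all 12 fits, with a median of 0.32 without KO replicate 1. Without KO replicate 3, 2 genes passed with limma, Lama5 and Tiam1, with log2 fold changes of -1.91 and -1.03 and adjusted p = 0.0304; both were named after their values were seen. The number of called lists ranged from 3 without KO replicate 1 to 7 without WT replicate 3, and was 1 with females only.

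**Figure D1:**
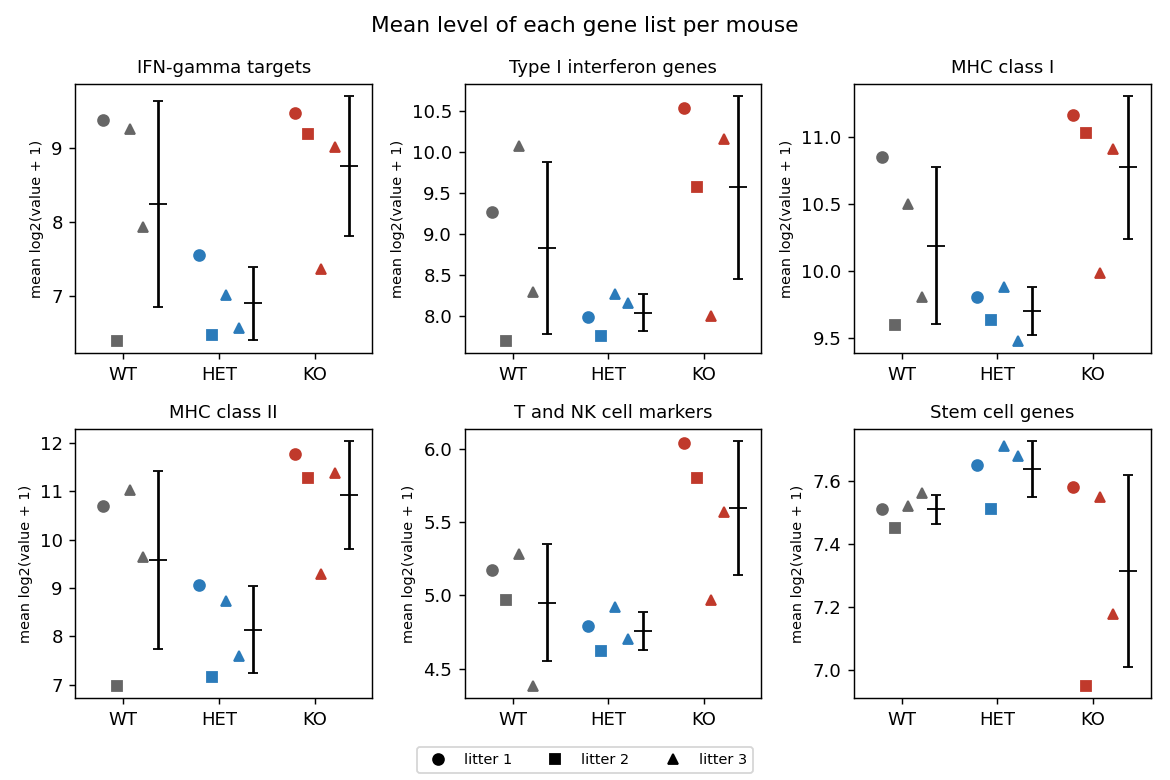
Mean log2(value + 1) of the members of 6 gene lists (vertical axes) in each mouse, by genotype, with symbols for litters 1, 2 and 3 and bars for the mean and SD of 4 mice. HET mice lie close together in the interferon gamma panel, between 6.48 and 7.56, while WT mice spread from 6.40 to 9.37.

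HET isolates had lower mean levels of interferon-inducible and antigen presentation lists than WT isolates, but the mice overlapped. WT replicate 2 lay below each HET mouse in the interferon gamma list (6.40 against at least 6.48). The same held in the type I (7.69 against at least 7.75) and MHC class II lists (6.97 against at least 7.17). The exact permutation p of the interferon and MHC list levels lay between 0.171 and 0.257. The interferon gamma list had 15 of 15 members lower, with a median log2 fold change of -1.48 and camera adjusted p = 2.3e-13. Ciita, the master regulator of class II transcription, was 41.5 ± 21.2 in HET and 210 ± 151 in WT, and the guanylate-binding protein gene Gbp2 was 190 ± 94.5 and 793 ± 555. The type I list had a median of -0.63 (camera adjusted p = 1.76e-07), the MHC class I list -0.49 (camera adjusted p = 0.000593) and the MHC class II list -1.76 (camera adjusted p = 0.000208). These 4 calls were lost at adjusted p = 0.766 with an estimated correlation, and 0 members passed with limma adjusted over the list alone or over all genes. Without WT replicate 1 the interferon gamma median was -0.80 and the MHC class I median -0.27, where the class I call was lost (camera adjusted p = 0.212). The type I median was -0.29 without WT replicate 3, and the MHC class II median -2.77 without WT replicate 2, where Ciita and Gbp2 had log2 fold changes of -2.77 and -2.53.

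The 5 genes with the smallest p in HET against WT were Csf1, Lefty1, DEFA6, Serping1 and Nos2, none past the threshold, with limma adjusted p = 0.988. Csf1, a macrophage growth factor, was 27.2 ± 4.54 in HET and 52.1 ± 13.5 in WT. Lefty1, a Nodal antagonist, was 37.7 ± 7.62 and 21.8 ± 7.08. Nos2, the inducible nitric oxide synthase gene, was 32.3 ± 6.17 and 119 ± 91.0, with a log2 fold change of -1.53 (SE 0.58). The complement regulator gene Serping1 had a log2 fold change of -1.16, and the defensin probe DEFA6 had 1.84 (SE 0.68), or 1.13 without WT replicate 2, with 1 WT mouse at the floor of the panel. The limma count past the threshold was 0 of 938 genes, with 22 genes at an unadjusted p under 0.05, 11 higher and 11 lower. The number of called lists ranged from 3 without WT replicate 1 to 7 without WT replicate 4.

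KO against HET showed the widest differences of the 3 comparisons. Camera called interferon-inducible, antigen presentation and T and NK cell lists as higher in KO, but not with an estimated correlation between genes. Il18 was lower in KO, and no single gene passed the threshold. The interferon gamma list had 15 of 15 members higher, with a median log2 fold change of 2.08. The type I list had a median of 1.52, and both had camera adjusted p = 1.85e-09. The MHC class I list had a median of 1.03 (camera adjusted p = 5.6e-06) and the MHC class II list 3.23 (camera adjusted p = 1.81e-05). H2-Aa was 24700 ± 14700 in KO and 1400 ± 1180 in HET, a log2 fold change of 4.24 (SE 1.32). H2-K1 had 1.47, Ciita 2.93, Gbp2 2.63 and Ifit1 1.68. The T and NK cell list had a median of 0.85, with camera adjusted p = 0.000262. The stem cell list had a median of -0.31, with camera adjusted p = 0.0435, and Lgr5 a log2 fold change of -0.89. All 6 calls were lost at adjusted p = 0.462 with an estimated correlation. The stem cell call was also lost in 6 of 12 fits that leave out 1 mouse (WT replicate 3, HET replicates 1 and 3, and KO replicates 2, 3 and 4), with a median of -0.16 and Lgr5 at -0.55 without KO replicate 2, and the other 5 lists kept theirs in all 12.

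Adjusted over the list alone, limma called 11 of 15 interferon gamma members, 15 of 26 type I members, 7 of 12 MHC class I members, 7 of 9 MHC class II members and 9 of 16 T and NK cell members, against 0 of each over all genes tested. Levels of the MHC class I, MHC class II and T and NK cell lists were higher in each KO mouse than in each HET mouse, at an exact permutation p of 0.0286, the smallest that 4 mice against 4 allow. The epithelial identity list was also higher, by 0.41, and the endothelium list was lower in KO, with a difference of -0.40, both at an exact permutation p of 0.0286. Over the 32 lists the lowest adjusted value of this permutation test was 0.183. The test moved mice across litters. Only 12 of the 35 splits of these mice keep litters balanced, so a permutation within litters could not give a p as low as 0.0286.

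The smallest p of single genes in KO against HET belonged to Il18, Sfrp1, Dusp8, Cd3e and Gzma, none past the threshold. Il18 was 1690 ± 240 in KO and 4150 ± 1370 in HET, with a log2 fold change of -1.24 (SE 0.22) and limma adjusted p = 0.132, and each KO mouse lay below each HET mouse. Sfrp1, a secreted Wnt antagonist, was 285 ± 149 and 31.7 ± 8.29, a log2 fold change of 2.88 (SE 0.67). The phosphatase gene Dusp8 was 41.1 ± 5.33 and 22.0 ± 7.68. Gzma had a log2 fold change of 3.17 (SE 0.80) and Cd3e 1.18 (SE 0.28). The last 4 had limma adjusted p = 0.248. The limma count was 0 of 938 genes, with 128 genes at an unadjusted p under 0.05, 98 higher and 30 lower in KO. In 62 genes the 4 KO values lay wholly above (46) or below (16) the 4 HET values, 6.61% of genes where chance gives 2.86% on average. The share was 1.17% in KO against WT and 1.81% in HET against WT. Genes vary together, so a single grouping can lie far from that average, and its spread was not computed. Without KO replicate 3, limma called 50 genes, 41 higher and 9 lower, among them Ccl5, H2-K1, H2-D1 and Sfrp1 higher and Il18 lower. Without HET replicate 4 it called Il18 and Dusp8.

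**Figure D2:**
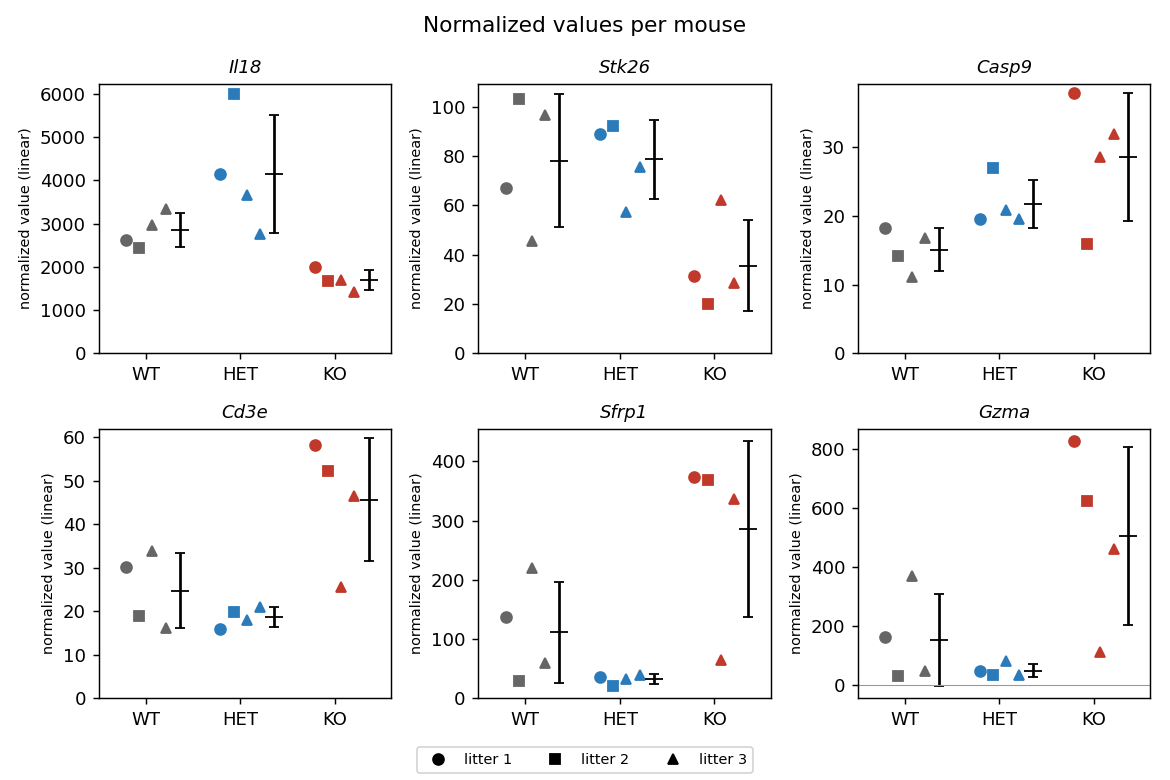
Normalized values (linear, vertical axes) of 6 genes in each mouse by genotype, with symbols for litters and bars for the mean and SD of 4 mice. Il18 in KO mice lay between 1412.2 and 1997.8, below all WT and HET mice, and Sfrp1 was 63.5 in KO replicate 3 against at least 336.3 in the other KO mice.

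By their medians, the interferon and antigen presentation lists lay above WT in KO isolates and below WT in HET isolates. The interferon gamma list was not called in KO against WT, and no list was called in either comparison with an estimated correlation. Over all 938 genes the KO and HET log2 fold changes against WT correlated at r = -0.41, where genes are not independent replicates, and 50.2% of genes had the same sign. Both comparisons share the WT mice, and groups simulated without an effect, with genes drawn independently, gave a mean r of 0.50, with 95% of simulations between 0.38 and 0.60. The covariance was -0.0686 against 0.0805 simulated. With the WT mice divided into separate pairs for KO and HET, r lay between -0.82 and -0.05. Of 100 random regroupings of the 12 mice, which keep the correlation between genes but not the litters, 2 gave an r as low. Of all 3240 assignments of the genotypes that keep the numbers in each litter, 88 (2.72%, the real one included) gave an r as low, with a median of 0.53; this set was chosen after the result was seen. Leaving out WT replicate 2 gave r = -0.02 and leaving out KO replicate 3 gave -0.58; without WT replicates 1, 3 or 4 or KO replicate 4 it was -0.25, -0.27, -0.23 and -0.25.

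The 2 panels measured 122 tested genes in common. Their log2 values correlated at a median r of 0.83 over the 12 mice. The KO against WT log2 fold changes from the panels correlated at r = 0.77 across genes, and their difference had an SD of 0.25. Each of the 12 mice matched its own assay on the other panel better than that of any other mouse, with r from 0.68 to 0.90.

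The authors' deposited table gave no gene with an adjusted p under 0.05 for KO or for HET against WT. Its adjustment is stricter than Benjamini-Hochberg. The lowest adjusted p in the authors' deposited table was 0.308 for KO and 1 for HET, with 200 and 95 of 1398 genes at an unadjusted p under 0.05. In the authors' deposited table, the smallest p-values for KO belonged to Wnt5a and Kdr, with log2 fold changes of -3.43 and -1.78, named here by that rank. Their unadjusted p-values in the authors' deposited table were 5.12e-05 and 5.64e-05. Adjusted by Benjamini-Hochberg over its 1398 genes, both would pass 0.05, so its count and the limma count rest on unlike adjustments. For genes on the immune panel only, the limma fold changes and those of the authors' deposited table correlated at r = 0.99 over 464 genes in both comparisons. For genes on the cancer pathway panel only, they correlated at r = 0.28 for KO and 0.08 for HET over 352 genes. The sign was the same for 50.6% of these genes for KO and 54.3% for HET, against 98.3% of the immune panel genes in both. Wnt5a had a limma log2 fold change of -0.58 for KO against WT. For KO, the authors' deposited table gave Casp9 -0.60, Alpi -0.13 and Pias1 -0.27, where limma gave 0.84, 1.15 and 0.58. Other named genes of this panel kept their sign. The authors' deposited table gave Lgr5 -0.93, Sox9 -0.64 and Sfrp1 2.28, where limma gave -0.40, -0.42 and 1.44. For HET, the authors' deposited table gave DEFA6 -1.98, where limma gave 1.84.

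**Figure D3:**
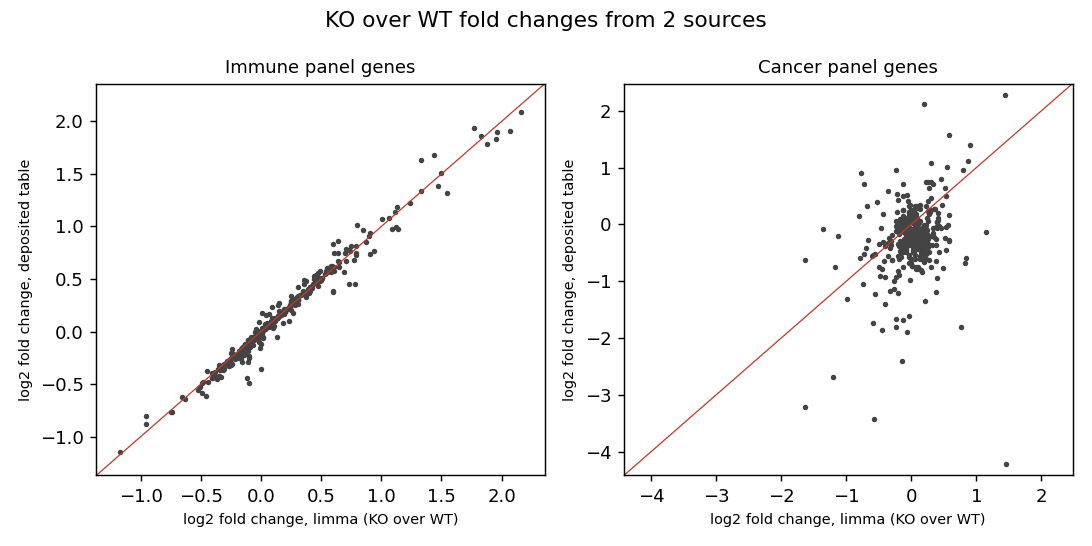
KO over WT log2 fold changes from the authors' deposited table (vertical axes) against those fitted with limma (horizontal axes), 1 point per gene, with the line of equal values. The 464 immune panel genes lie along the line (r = 0.99) and the 352 cancer pathway panel genes do not (r = 0.28).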

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

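All tests weighed in this part were chosen after the results were seen. Among 456 groups of 4 mice (levels of 32 lists and named genes in 3 genotypes), 16 held a mouse whose gap to the others exceeded the critical share of the group's range; chance gives about 1 in 20. KO replicate 3 was the low mouse for Sfrp1 (gap share 0.941) and H2-Aa (0.870). WT replicate 1 was high for Lyz1 (0.935) and low for Cx3cl1 (0.830), Thbs4 (0.899), Relb (0.850) and Rel (0.912). WT replicate 2 was low for Cdc7 (0.899), and WT replicate 3 was high for Gadd45b (0.936). KO replicate 4 was low for Sox9 (0.856), Fn1 (0.882) and the fibroblast and smooth muscle list (0.933). KO replicate 2 was low for Jun (0.869), and HET replicate 2 was low for Id2 (0.960). HET replicate 4 was high for the immediate early list (0.902) and HET replicate 3 for the granulocyte and mast cell list (0.969).

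Interferon gamma list levels overlapped between genotypes, with KO replicate 3 at 7.37 and WT replicate 3 at 9.25, females of 1 litter. Exchanging their labels gave 68 genes past the limma threshold in KO against WT, 34 of them outside the interferon, MHC and T and NK cell lists, and 154 with litter as a block, where each of the other 15 exchanges of a WT and a KO mouse gave 0 with and without it. An exchange is a candidate explanation, but WT replicate 1 at 9.37 would still lie among the KO mice. Exchanging a low KO mouse with a high WT mouse was also bound to widen the interferon difference. The rise in called genes is therefore no separate support for an exchange. KO replicate 3 minus WT replicate 3 correlated with the difference of the other 6 mice at -0.59 over the 863 genes outside these lists, the lowest of 16 pairs, but at -0.06 over the 485 of them only weakly related to the interferon gamma list (range of all pairs -0.47 to 0.27), so an exchange and an interferon response that varies within genotypes cannot be told apart. Litter left 0.91 of the residual SD of the list level, which argues against litter as the whole cause. Centring on the reference genes left a range of 3.15 among WT mice against 2.97 before, which argues against assay scaling as the whole cause. The centring began from the authors' normalized values, so their background step was not tested. The genotype labels were not checked with Ptpn2, and no biological explanation for the spread within genotypes was tested.

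Chance could not be excluded for the counts of the comparisons. As many genes at an unadjusted p under 0.05 as in KO against WT (27) came from 23 of the 35 splits of those 8 mice, with up to 198 in another split. For HET against WT (22) it was 20 of 35 splits, with up to 188, and for KO against HET (128) 6 of 35, with up to 245. These 3 largest counts came from the splits that set litters 1 and 2 against litter 3, so they follow a structure of the samples. Among the 12 splits that keep litters balanced, KO against HET had the highest count, with 111 the highest of the others. As many called lists came from 16 of 35 splits for KO against WT (5 lists, up to 8 elsewhere), from 15 for HET against WT (4, up to 8) and from 11 for KO against HET (6, up to 15). Among the 12 splits that keep litters balanced, it was 6, 6 and 5, the real split included.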

How the results depend on the processing

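Fits with reference-gene centring, exact permutation of list levels, and KO replicate 3 and WT replicate 3 both left out were chosen after seeing the data. The consolidated table and the Ptpn2 result were not run. The count of genes with limma adjusted p under 0.05 stayed at 0 in HET against WT in all settings. In KO against HET it was 1 without a filter on low values (Spp1, named after its value was seen), 1 with quantile normalization (Il18), and from 0 to 50 over the fits that leave out 1 mouse. In KO against WT that range was 0 to 2. With both mice left out, the counts were 27 in KO against WT and 88 in KO against HET. The cause was not tested.

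The called lists (5, 4 and 6 of 32) fell to 0 in each comparison with an estimated correlation, with fry (lowest adjusted p 0.509, 0.909 and 0.145) and with exact permutation (0.813, 0.875 and 0.183). Leaving out 1 mouse gave 3 to 7 lists in KO against WT, 3 to 7 in HET against WT and 5 to 6 in KO against HET; females only gave 1 in KO against WT. With the litter as a fixed block, genes called stayed at 0 and lists were 5, 4 and 7; as a random block, 0 genes and 5, 4 and 7 lists. The block moved none of these counts by over 1.5 times. None of the 44 gene results and 15 called list results refitted here reversed.

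The correlation of KO and HET fold changes was -0.24 without a filter and from -0.58 to -0.02 over fits that leave out 1 mouse. The 2-panel correlation was 0.72 without a filter, 0.72 with median centring and 0.90 with reference-gene centring; the cause was not tested. With 4 mice per group the median half-width of a 95% interval was 0.57 on the log2 scale, which limits what these fits can show. Genes near the panel floor are limited further.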

Other observations

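Median and quantile scaling were planned; every other test in this part, and the use of these scalings as a test of an explanation, was chosen after the results were seen. The main axis of variation across the 12 mice, with 50.8% of the variance, was led by the interferon-induced genes Ifi44 and Ifi44l and the class II genes H2-Aa, Cd74 and H2-Eb1, named here by their rank on this axis after it was seen. The T and NK cell list followed the interferon gamma list over the mice (r = 0.74, permutation p = 0.00524, adjusted p = 0.00873 over 5 relations; rho = 0.69, permutation p = 0.0151). The permutation moved all 12 mice freely, so its p also holds differences between genotypes and litters. The correlation of the T and NK cell list was 0.64 within genotypes and 0.77 within litters, for which no p was computed. It was 0.65 in the 6 mice of litter 3 and 0.63 without the 2 farthest mice. The MHC class II, type I and stem cell lists gave r = 0.97, 0.91 and -0.45 with the interferon gamma list. The MHC class II and interferon gamma lists share Ciita, so their r is not between separate genes. The macrophage and dendritic cell list gave r = 0.34 (permutation p = 0.277; rho = 0.29, permutation p = 0.365).

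Haemoglobin transcripts varied between mice of every genotype. Hba-a1 was 97.2 in KO replicate 4 and 2464.7 in HET replicate 3, and Hbb-b1 was 87.7 and 953.2 in the same mice. Group means of Hba-a1 were 587 ± 549 in WT, 1190 ± 866 in HET and 666 ± 540 in KO (SD, n = 4). The 4 haemoglobin genes had HET against WT log2 fold changes from 1.03 to 1.27, none past the threshold (limma adjusted p = 0.988), and whether blood RNA bears on the lower interferon lists of HET was not tested. The collagen gene Col1a1 ranged from 7.1 in KO replicate 4 to 148.6 in WT replicate 1. Uty, on the Y chromosome, was 375.0 in WT replicate 4 and 506.6 in HET replicate 4, the males, and at most 2.6 in the other mice. These genes were chosen after their values were seen.

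Higher interferon and antigen presentation genes in KO than in HET mice kept their camera call under median, quantile and reference-gene scaling. The lowest median of the interferon gamma list was 1.83. The scalings moved the median of all genes by -0.06, -0.10 and 0.05, small beside that list. Camera compares a list with the other genes, so a shift of all genes could hardly lose a call. The scalings also began from the authors' normalized values, so they cannot decide on the authors' normalization. The camera calls do not hold under an estimated correlation (adjusted p = 0.462), fry or exact permutation. The macrophage and dendritic cell list differed by 0.08 (SE 0.20) while the MHC class II list differed by 2.79 (SE 0.72). This argues against RNA of those cells as the main source. Of the 9 members of the macrophage and dendritic cell list, 4 were higher and 5 lower in KO. Some lay near the panel floor, such as Clec4e at 21.0 in KO and 25.2 in HET, so a smaller share is not excluded. Relative to the mean of the other 5 lists of non-epithelial cells, the T and NK cell list was higher in KO by 0.91 (SE 0.22). Camera had already called that list in these mice, so its excess is no separate support. The levels of the other 5 lists differed by -0.40 to 0.16, so non-epithelial markers did not rise alike. A gain of T and NK cells alone would also lower the epithelial share. The epithelial identity list was instead higher in KO by 0.41, with 3 of 3 members higher, though camera did not call it. The goblet cell list differed by -0.23. With so few members, a gain of T and NK cells is not excluded. A difference in interferon response between the genotypes may remain, as a hypothesis. In KO mice the MHC class II list lay at 10.93 (SD 1.12) and the T and NK cell list at 5.59 (SD 0.46). These levels argue against T and NK cells as the main source of the class II genes. For the other lists it stays open whether epithelium or T and NK cells would carry such a difference. The same genes measured in sorted cells of both kinds would decide it. Chance was not excluded, since 11 of 35 splits called as many lists, and 5 of the 12 that keep litters balanced, the real one included in both.

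Fold changes of cancer pathway panel genes in the authors' deposited table differed from those of the panel's values. Any assignment of the mice to genotypes is a linear combination of their values, and the best combination gave an R squared of 0.523 for these genes against 0.981 for immune panel genes, which argues against other labels. A single shift by another normalization would keep the correlation high, and it was 0.28. Low signal would matter less in genes with a mean of at least 200, where the correlation was 0.17 for KO. For HET it was 0.47 against 0.08 over all genes of the panel, so low signal is not excluded as part of the HET difference. What values entered the authors' deposited table for this panel stays open, and no biological explanation was tested.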
